A study of Mus musculus with 6 samples.

How the data were processed

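The series holds 6 single-colour expression arrays of total RNA from mouse colon, 3 labelled proximal and 3 labelled distal. Per the labels' protocols, tissue was homogenised in Trizol, RNA was amplified to complementary DNA with NuGEN Ovation kits, and the product was fragmented and labelled with biotin. Per the submitters' processing notes, the authors made the deposited values with RMA in Partek 6.5. The deposited values are taken as log2 expression per probe set, from that note and from their range of 2.91 to 15.16. The background setting, the version of RMA and the statistical model are not given in the sources used here, and no scanner files were used here. RMA makes the arrays' distributions alike, so a shift shared by most genes would not be seen. Values carry 2 decimals.

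The table has 45101 probe sets, of which 64 are control probe sets and were left out of all gene tests. Of the others, 34945 have 1 gene symbol, 932 have several and were not named, and 9160 have no gene listed. Symbols were updated through the gene identifier for 34741 probe sets with a RefSeq gene table of the assembly GRCm38.p6, used for names only, and 204 kept the array's symbol. A gene was represented by the probe set with the highest mean over all 6 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Of the genes called in the 4-library fit, 1837 had more than 1 probe set, and in 1383 of these all probe sets had the same direction. Among genes named in the results, not all probe sets had the same direction for Aqp11, Fkbp5, Lipe, Ndufs4, Sc5d, Tnfrsf19 and Tyms, which passed, and for Dsp, Mylk, Pla2g1b, Stmn3, Tpm1, Tpm2 and Zg16, which did not.

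Libraries were grouped by the tissue in their labels and named by the number in their titles. The design text says that 3 animals gave both tissues, but not which numbers share an animal. Distal and proximal libraries were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided, Benjamini-Hochberg adjustment over all genes, adjusted p threshold 0.05), without a block for the number. All differences are distal minus proximal on the log2 scale, and p-values measure the spread between these libraries.

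The 41 gene lists, 20 of cell type markers and 21 of pathways, were written before the data were examined, as were the tests, the rule for named genes and the first set of alternatives. Of 1241 list entries 1134 were measured. Each list with at least 5 measured genes was tested with limma's camera at a preset inter-gene correlation of 0.01, which compares the list with all other genes, and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. With so few libraries, the estimated correlation leaves camera few degrees of freedom and little power. A list that does not pass it is therefore not shown to be unshifted. The preset correlation can in turn understate how genes of a list vary together, and so overstate a shift. The order of Hox genes was tested with Spearman's rho of paralog number against the difference, with 100000 permutations, two-sided.

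Genes were named by rule: the 12 with the largest difference in each direction among genes past the threshold whose groups do not overlap, leaving out predicted and clone names; up to 4 genes of each list with the smallest adjusted p; all Hox genes and aquaporins past the threshold; and the 3 brightest genes of 8 lists of other tissues or cells. As labelled no gene passed, so the rule was also applied to the 4-library fit. Ins2 and Iapp, markers of pancreatic islets, and Retnlb and Ang4 were chosen after their values were seen.

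The alternatives set in advance were the replicate number as a block, leaving out genes with a mean below 9.31 (9099 genes kept), the mean of a gene's probe sets, quantile normalization, median centring, a trended and robust variance prior, leaving out each library in turn, a plain test with a pooled variance per gene, each probe set on its own, array weights, and an adjusted p threshold of 0.01. For lists, camera on ranks was added, and for the Hox order Pearson's r. The fit of 4 libraries, without those labelled proximal 1 and distal 3, was chosen after seeing the data, as were its own leave-one-out and scaling alternatives. It assigns no library to another label.

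The calculation was tested on simulated data for 18193 genes with 200 changed. With 6 arrays and the spread within the labelled groups, 53% of 2-fold and 87% of 4-fold changes were recovered. With the spread of the 4 libraries these shares were 85% and 95% for 6 arrays, and 43% and 74% for 4 arrays. The changed genes were drawn at random, so the shares do not hold for regional genes, whose spread within the labelled groups was far larger (SD 3.98 for Hoxb13). With 6 arrays, 3494 changed genes and 1 label of each group exchanged, 0 genes were called, and the median ratio of estimated to true difference was 0.332. For lists, 1 raised list ranked 1 and 0 others were called. Values were arranged with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.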

Results

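Gene expression was measured in the large intestine of untreated female mice of the inbred strain C57BL/6J, to compare tissue of the proximal colon with tissue of the distal colon. There were 3 libraries labelled proximal and 3 labelled distal, and per the design text 3 animals gave both regions. Each library was hybridised to 1 array, and 18193 genes were tested on the log2 scale of the deposited values. The array medians were 7.97, 7.92 and 7.93 for the libraries labelled proximal 1, 2 and 3, and 7.96, 8.02 and 7.90 for those labelled distal 1, 2 and 3. The number of arrays limits the precision, and no detection calls were used here. Samples are named by their labels, as "the library labelled proximal 1", because the profiles of a pair of libraries went against the labels.

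Regional genes separated the 6 libraries, but not along the labels. Hoxb13, a homeobox gene of the hindmost body axis, measured 13.39 in the library labelled proximal 1 and 6.53 and 6.48 in those labelled proximal 2 and 3. It measured 13.78 and 13.29 in the libraries labelled distal 1 and 2, and 6.65 in the library labelled distal 3. Slc51a, a subunit of the basolateral bile acid exporter, ran the other way, with 5.83 in the library labelled proximal 1, 12.47 and 12.39 in proximal 2 and 3, 5.07 and 5.94 in distal 1 and 2, and 12.05 in distal 3. Across the 18193 genes, the library labelled proximal 1 correlated at r = 0.994 with distal 1 and 0.990 with distal 2, against 0.977 with proximal 2 and 0.975 with proximal 3. The library labelled distal 3 correlated at r = 0.996 with proximal 2 and 0.995 with proximal 3, against 0.974 with distal 1 and 0.976 with distal 2. These correlations run across genes, which are not independent replicates. The first principal component held 73.4% of the variance, with scores of 34.3, 45.0 and 38.8 for proximal 1, distal 1 and distal 2, and of -40.7, -43.1 and -34.4 for proximal 2, proximal 3 and distal 3.

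**Figure D1:**
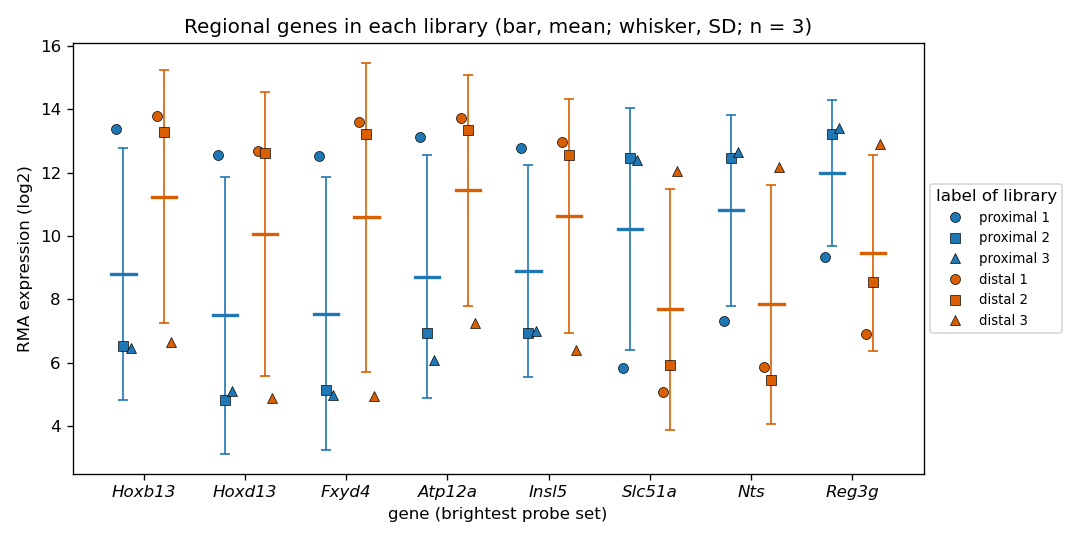
RMA expression (log2, vertical axis) of 8 genes in each of the 6 libraries, coloured by label and shaped by replicate number; bars are means and whiskers SDs of 3 libraries. Hoxb13, Hoxd13, Fxyd4, Atp12a and Insl5 lie high in proximal 1, distal 1 and distal 2, and Slc51a, Nts and Reg3g lie high in proximal 2, proximal 3 and distal 3.

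As labelled, no gene passed the test between distal and proximal colon. Examples among the regional genes show how: Hoxb13 averaged 11.24 ± 3.98 (SD, n = 3) in distal and 8.80 ± 3.98 (SD, n = 3) in proximal libraries, a difference of 2.44 (SE 2.58, limma adjusted p = 0.833). Fxyd4, a regulator of the sodium pump, differed by 3.04 (SE 2.99, limma adjusted p = 0.826), and Nts, which encodes the gut peptide neurotensin, by -2.97 (SE 2.22, limma adjusted p = 0.824). In all, limma called 0 of 18193 genes at an adjusted p of 0.05, with a smallest adjusted p of 0.824. At an unadjusted p of 0.05 there were 554 genes, 164 higher in distal and 390 higher in proximal libraries, and this split became 375 and 247 when each array was centred on its median. A plain test with a pooled variance per gene called 0, with 607 at an unadjusted p of 0.05. Chance alone gives a share of 0.05 of the genes tested, and both 554 and 607 lie below it. The 3 distal and 3 proximal values did not overlap for 1334 genes (7.33%), where chance gives 10%. With array weights, which gave proximal 1 and distal 3 weights of 0.322 and 0.291 against 6.72 for proximal 2, limma called 5579 genes, 2227 higher in distal and 3352 higher in proximal libraries. The weights were 1.57 for proximal 3, 2.50 for distal 1 and 0.403 for distal 2.

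In the unweighted fit of the 6 libraries as labelled, the interferon response was the only list with members that passed when adjusted over the list alone. Of its 31 measured genes 0 passed over all genes tested, and 4 passed adjusted over the list alone, namely Iigp1, Zbp1, Cxcl9 and Psmb9. Their differences were -0.90 (SE 0.19), -1.20 (SE 0.29), -1.79 (SE 0.44) and -0.67 (SE 0.16), lower in distal libraries, each with a limma adjusted p of 0.824 over all genes. The list's median deviation from each gene's mean was 0.66 and 1.01 in the libraries labelled proximal 2 and 3, and -0.19, -0.60, -0.30 and -0.48 in proximal 1 and distal 1, 2 and 3.

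By camera with a preset inter-gene correlation of 0.01, 13 of 41 lists shifted relative to all other genes as labelled, 12 towards proximal and 1 towards distal. The interferon list (adjusted p = 2.30e-16), macrophages and dendritic cells (1.10e-08), T and innate lymphocytes (0.000409), immediate early and heat shock genes (0.00339) and endothelium (0.0127) shifted towards proximal. So did fatty acid oxidation (0.0127), xenobiotic metabolism (0.0176), small intestinal epithelium (0.0184), cell division (0.0184), oxidative phosphorylation (0.0228), lipid absorption (0.0477) and antigen presentation by MHC class II (0.0477). Smooth muscle shifted towards distal (adjusted p = 1.15e-08), with a median difference of 0.20 over 38 genes. With an estimated correlation, each of the 13 had an adjusted p = 0.796, and 0 of 41 lists passed. By fry 0 lists passed, with a smallest adjusted p of 0.809 for shifts in one direction and 0.713 for changes in either. The sign of the median, the mean and the test was not the same for 12 lists, and 0 of these passed. Of the 41 lists, 28 did not pass with the preset correlation, with adjusted p from 0.0876 to 0.992.

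Without the libraries labelled proximal 1 and distal 3, 3494 of 18193 genes differed (limma, adjusted p of 0.05), 1402 higher in distal and 2092 higher in proximal libraries, 1138 of them at least 2-fold. This alternative was chosen after seeing the data. Both libraries were left out for their own expression profiles, so its p-values overstate the evidence and describe only these 4 libraries, 2 per label. All differences from here on are distal 1 and 2 minus proximal 2 and 3. The share of called genes higher in distal libraries was 40.1% as deposited, 50.2% after quantile normalization and 54.7% after median centring. Of the calls after quantile normalization and median centring, 3112 and 2959 were among the 3494 with the same sign, and the median difference of all genes moved from -0.045 to 0.007 and 0.045. With 1 of the 4 libraries left out, 1 residual degree of freedom remained, and the lone library was assumed to vary like the pair of the other label. The count was then 165 without proximal 2, 146 without proximal 3, 1633 without distal 1 and 405 without distal 2, of which 165, 146, 1368 and 375 were among the 3494 with the same sign. Of 1134 list members 419 passed over all genes, and 491 passed adjusted over the list alone. The counts of list members below are to be read beside the 3494 calls among 18193 genes, a share that some lists come near or fall below. By camera 19 of 41 lists shifted with the preset correlation and 0 with an estimated one, and by fry 15 lists passed in one direction and 38 in either. Below, a list is said to shift or pass by camera with the preset correlation, and fry in one direction could differ. By fry, mucin type glycosylation (adjusted p = 0.0104) and crypt base markers (0.0249) passed, though not by camera. The interferon (0.0666) and smooth muscle (0.153) lists did not pass by fry, though they did by camera. The sign of the median, the mean and the test was not the same for 9 lists, 0 of which shifted. Across the 3494 genes, the library labelled proximal 1 lay nearer the distal pair in 75.6%, and the library labelled distal 3 nearer the proximal pair in 90.1%.

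The genes with the largest differences, 12 in each direction, were named by rule. Higher in distal libraries were Fxyd4 (8.34, SE 0.16), Hoxd13 (7.68, SE 0.14), the transglutaminase Tgm3 (7.21, SE 0.15), Hoxb13 (7.03, SE 0.18) and Atp12a, the colonic proton-potassium pump (7.02, SE 0.30). They were followed by Sval1 (6.10), the fucosyltransferase Fut9 (5.96), Insl5, a peptide hormone of colonic endocrine cells (5.78), the serine protease Tmprss13 (5.76), Casp14 (5.69), Cyp2f2 (5.08) and Cyp2d12 (4.96). Higher in proximal libraries were Slc51a (-6.93, SE 0.29), Nts (-6.88, SE 0.18), the glycosyltransferase Ugt8a (-6.46, SE 0.13), the antibacterial lectin Reg3b (-6.45, SE 0.40) and Prap1 (-5.82, SE 0.12). The others were Ugt2b5 (-5.67), the apolipoprotein Apoa1 (-5.67), Cyp3a25 (-5.65), the lectin Reg3g (-5.59), Epop (-5.26), the peroxisomal thiolase Acaa1b (-5.18) and the acute phase protein Saa3 (-5.09). The limma adjusted p of these 24 genes ran from 9.86e-05 for Fxyd4 to 0.00613 for Ugt2b5. In 13 of the 24 genes the lower pair averaged below 6.54, the lower quartile of all gene values, where background signal can hide lower levels, so those differences are at best lower bounds and the order by size is not settled. The same limit holds for genes named below with such a lower pair, among them Slc10a2 (3.43), Npc1l1 (4.72), Rdh1 (3.88), Olfm4 (4.39) and Hoxc8 (3.83). All probe sets of each of the 24 genes had the same direction, with more than 1 probe set for 8 of them. The probe sets of Slc51a, Reg3b and Epop are of a kind that can match several transcripts, and the Cyp and Ugt genes belong to families with similar sequences, so their levels can include relatives. The library labelled proximal 1 lay nearer the distal pair, and the library labelled distal 3 nearer the proximal pair, in all 24 genes, with 12.53 for Fxyd4 in proximal 1 and 12.19 for Nts in distal 3.

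Hox genes differed in both directions. Of 14 measured posterior Hox genes, 5 were higher in distal libraries, 2 were lower and 7 did not pass. Beside Hoxd13 and Hoxb13, the higher ones were Hoxa13 (1.89), Hoxd11 (1.72) and Hoxd10 (1.08), and the lower ones Hoxc10 (-2.62) and Hoxd9 (-0.65). Of 19 anterior Hox genes, 8 were lower in distal libraries, namely Hoxb6 (-4.31), Hoxc8 (-3.07), Hoxb4 (-2.56), Hoxb3 (-2.45), Hoxb5 (-2.03), Hoxd8 (-2.0), Hoxd3 (-1.87) and Hoxb2 (-1.81). Hoxa5 (0.99), Hoxa3 (0.77) and Hoxa2 (0.67) were higher, and 8 did not pass. The anterior list shifted towards proximal (camera adjusted p = 0.0251, and adjusted p = 0.571 with an estimated correlation), and the posterior list did not pass (0.0515). Across 33 Hox genes, Spearman's rho of paralog number with the difference was 0.34 in the 4 libraries (permutation p = 0.052, two-sided) and 0.29 as labelled (permutation p = 0.10). Pearson's r as labelled was 0.43 (permutation p = 0.0088). Hox genes are not independent replicates, so these values only describe an order across genes.

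**Figure D2:**
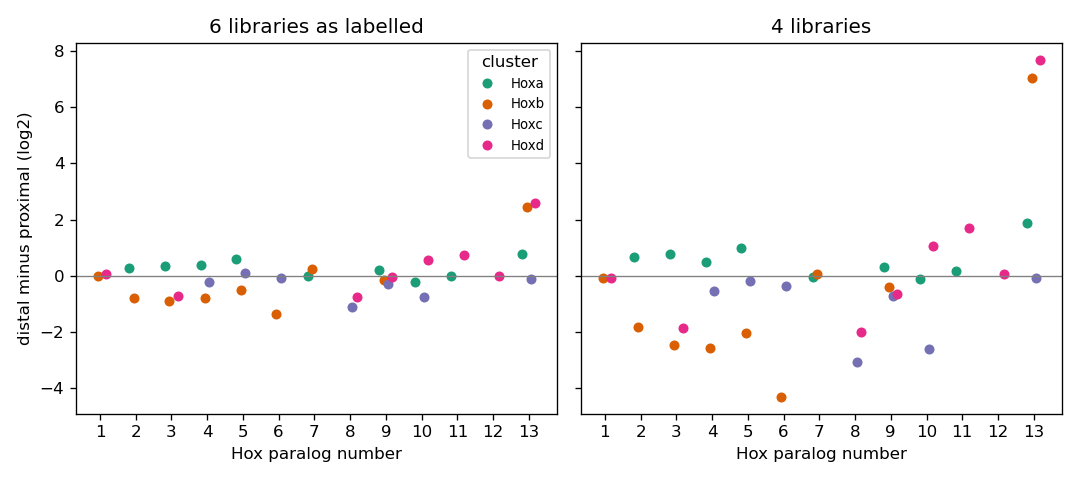
Difference between distal and proximal libraries (log2, vertical axis) against Hox paralog number for 33 genes, 1 point per gene, coloured by cluster, for the 6 libraries as labelled (left) and for the 4 libraries (right). In the 4 libraries, Hoxb13 and Hoxd13 stand highest at 7.03 and 7.68 and Hoxb6 lowest at -4.31.

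Of 14 bile acid genes 6 were higher in proximal and 0 in distal libraries, and 8 did not pass. The higher ones include Slc10a2, the apical sodium-dependent bile acid transporter (-3.86, SE 0.14), Fabp6, a bile acid binding protein (-3.06, SE 0.15), and Slc51b (-1.59, SE 0.13). Of 28 lipid absorption genes 16 were higher in proximal and 2 in distal libraries, while 10 did not pass, and those higher in proximal libraries include the cholesterol transporter Npc1l1 (-4.19, SE 0.11) and the fatty acid transport proteins Slc27a2 (-2.71) and Slc27a4 (-1.94). Of 31 small intestinal epithelial markers 18 were higher in proximal and 1 in distal libraries, for example the matrix protease Mmp7 (-3.21) and the peptidase Anpep (-2.72). Of 32 absorptive colonocyte markers 12 were higher in proximal and 3 in distal libraries, with Tmigd1 (-3.73), Clca4b (-3.52), Clca4a (-1.37) and the peptide Guca2b (-1.22) leading. The camera adjusted p was 0.00531, 7.04e-06, 1.41e-06 and 0.00712 for these lists in that order, and with an estimated correlation the adjusted p = 0.571 for each. The lists share genes, so their counts and tests are not separate evidence. Slc10a2 and Fabp6 are in the bile acid and small intestinal lists, Apoa1 and Mttp in the lipid and small intestinal lists. Fabp2 is in the lipid, small intestinal and colonocyte lists.

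Transport of salt, water and nutrients differed gene by gene. Of 16 genes of electrogenic sodium absorption 4 were higher in distal and 2 in proximal libraries, with the epithelial sodium channel subunits Scnn1a (1.22, SE 0.11) and Scnn1g (1.65, SE 0.29) among the former and Fkbp5 (-1.03) among the latter. Of 27 genes of electroneutral salt, bicarbonate and proton transport 7 were higher in distal and 6 in proximal libraries, with the chloride channel Ano1 (1.70) and the carbonic anhydrase Car13 (-2.07) as examples. The water channels Aqp4 (2.50), Aqp11 (-1.60), Aqp8 (-0.72) and Aqp1 (-0.49) passed, and 7 of 11 aquaporins did not. Of 33 nutrient, vitamin and short chain fatty acid transporters 7 were higher in distal and 9 in proximal libraries, including the calcium channel Trpv6 (2.56), the peptide transporter Slc15a1 (2.09), the glutamate transporter Slc1a1 (1.97) and the amino acid transporter Slc6a19 (-2.99). As lists, none of these shifted (camera adjusted p = 0.115, 0.427, 0.290 and 0.997).

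Of 69 xenobiotic metabolism genes 39 were higher in proximal and 6 in distal libraries, with the carboxylesterase Ces1g (-4.67, SE 0.16) and the cytochrome P450 Cyp2c68 (3.85, SE 0.15) as examples. Of 29 genes of fatty acid oxidation and ketone synthesis 15 were higher in proximal libraries, such as Pdk4, a kinase of pyruvate dehydrogenase (-2.66), and Acot1 (-1.75), and 1, Acsm3 (1.45), was higher in distal libraries. Of 38 oxidative phosphorylation genes 4 were higher in proximal libraries, namely Cycs (-0.73), Uqcrfs1 (-0.51), Ndufs4 (-0.47) and Ndufa10 (-0.46). These lists shifted towards proximal (camera adjusted p = 1.07e-07, 2.03e-07 and 0.00326), with adjusted p = 0.571 for each with an estimated correlation. Of 27 retinoid genes 7 were higher in proximal and 4 in distal libraries, with Rdh1 (-3.90), Aldh1a1 (-2.06), Adh1 (2.27) and Rdh16 (1.93), and the list did not pass (0.119). Of 20 cholesterol synthesis genes only Sc5d passed (-0.63), and that list did not pass either (0.737).

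Of 30 goblet cell markers 8 were higher in distal and 0 in proximal libraries, including Rep15 (1.52), Ttc39a (1.07), the transcription factor Creb3l1 (0.99) and Bcas1 (0.82), and the list shifted towards distal (camera adjusted p = 0.00500, and adjusted p = 0.684 with an estimated correlation). Of 46 genes of mucin type glycosylation 13 were higher in distal and 9 in proximal libraries, with the glycosyltransferases B3gnt7 (4.49), B3gnt5 (3.47) and St3gal6 (3.20), and the list did not pass (0.0576). Of 31 enteroendocrine markers 9 were higher in distal and 4 in proximal libraries, where Insl5 and the transcription factor Isl1 (2.14) opposed Nts and Sct, which encodes secretin (-3.73). Of 40 antimicrobial genes 7 were higher in each direction, among them Mptx1 (4.32) and Reg3a (-3.02). Of 25 tuft cell markers 3 were higher in distal and 6 in proximal libraries, such as Lrmp (1.53), Spib (0.92), the succinate receptor Sucnr1 (-1.60) and Siglecf (-1.06). Of 25 crypt base markers 5 were higher in distal and 6 in proximal libraries, with Smoc2 (0.75), Olfm4 (-4.75), Msi1 (-1.31) and Tnfrsf19 (-0.79). As lists, the last 4 groups did not shift (camera adjusted p = 0.325, 0.759, 0.737 and 0.564).

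Single genes of transcription factors, signals and cell division also passed. Among all genes tested 3494 of 18193 passed, so such counts do not by themselves set these groups apart. Of 25 gut transcription factors 4 were higher in proximal and 2 in distal libraries, with Isx (-4.17), Creb3l3 (-2.55), Gata5 (-1.43) and Foxa2 (0.82), and the list did not shift (camera adjusted p = 0.625). Of 42 Wnt, BMP and hedgehog genes 7 were higher in distal and 3 in proximal libraries, including the Wnt antagonists Frzb (1.72) and Sfrp1 (0.86), the BMP antagonist Grem1 (1.54) and the ligand Ihh (-0.86), without a shift of the list (0.539). Of 39 cell division genes 5 were higher in proximal libraries, among them Aurka (-0.65), Rrm2 (-0.65), Cdk1 (-0.61) and Tyms (-0.49), and the list shifted (0.00430, with an adjusted p = 0.706 with an estimated correlation). For Tyms 1 of 4 probe sets had this direction. Of 26 immediate early and heat shock genes 6 were higher in proximal and 1 in distal libraries, with Fosl1 (-3.02), Hspa1a (-1.40), Atf3 (-0.93) and Egr1 (-0.92), and the list shifted (0.0487, with an adjusted p = 0.571 with an estimated correlation).

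Lymphocyte markers split by lineage. Of 35 B lymphocyte and plasma cell markers 17 were higher in distal and 0 in proximal libraries, including Fcmr (2.51), Ms4a1 (2.18), Cd22 (1.70) and Cd79b (1.65). Of 32 T and innate lymphocyte markers 18 were higher in proximal and 1 in distal libraries, including the protease Gzmb (-3.12), Cd3g (-2.39), the chemokine Xcl1 (-2.0) and Cd3e (-1.33). Both lists shifted (camera adjusted p = 1.52e-08 and 1.12e-06), with an adjusted p = 0.571 for each with an estimated correlation. Of 32 macrophage and dendritic cell markers 11 were higher in proximal libraries, with Ccl8 (-1.71), C1qa (-1.40), Ccl9 (-1.27) and the receptor Fcgr1 (-0.99), and the list shifted (0.000463, with an adjusted p = 0.706 with an estimated correlation). Of 31 interferon response genes 23 were higher in proximal libraries, such as Ifit1 (-3.86), Ifit2 (-3.21), Ifit3 (-2.52) and Oasl1 (-2.41), and the list shifted (1.89e-09, with an adjusted p = 0.579 with an estimated correlation). The library labelled distal 3, otherwise near proximal 2 and 3, lay nearer the mean of proximal 2 and 3 in only 2 of these 23 genes, with 10.04 for Ifit3 against 12.03 and 12.56 in proximal 2 and 3. Of 9 MHC class II genes 2 were higher in distal and 1 in proximal libraries, H2-Ob (1.76), H2-DMb2 (1.04) and H2-DMa (-0.89), without a shift (0.737). Of 16 mast cell and eosinophil markers 1 was higher in distal and 3 in proximal libraries, with Cma1 (1.62), Mcpt2 (-2.26) and Fcer1a (-0.60) beside Siglecf, also without a shift (0.249). Fcer1a measured only 3.71 to 4.54 across the libraries, so its difference lies near the floor.

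Of 38 smooth muscle markers 7 were higher in distal libraries, including Synm (0.98), Itga8 (0.91) and Fhl1 (0.86), and Pcp4 was lower (-1.13). Of 34 fibroblast and matrix markers 4 were higher in distal and 1 in proximal libraries, with Fbln1 (0.97), Fn1 (0.71), Bgn (0.66) and Mfap4 (0.55). Of 37 enteric neuron markers 5 were higher in distal and 2 in proximal libraries, including Ass1 (1.14), Elavl3 (0.90), Nefl (-1.28) and the peptide Cartpt (-0.93). Ass1 measured 4.87 to 6.22 across the libraries, below the lower quartile of 6.54, so its difference lies near the floor. These lists shifted towards distal (camera adjusted p = 7.04e-06, 0.0251 and 0.0134), with adjusted p = 0.684, 0.706 and 0.706 with an estimated correlation. Of 10 markers of interstitial cells of Cajal, the pacemaker cells of the gut, 2 were higher in distal and 3 in proximal libraries, with Thbs4 at 4.94, Edn3 at -1.66 and Kcnj8 at -0.62. Of 17 glial markers 1 passed, the endothelin receptor Ednrb (-1.77), and of 25 endothelial markers 2 passed, Emcn (-0.65) and Aqp1. None of these 3 lists shifted (camera adjusted p = 0.904, 0.904 and 0.417).

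Markers of other tissues were present at different levels. The adipocyte genes Car3, Fabp4 and Lpl reached 13.51, 13.23 and 12.89 in their highest libraries, and of 17 adipocyte markers 5 were higher in proximal and 1 in distal libraries, including Cidec (-2.67), the nuclear receptor Pparg (-1.92), Lipe (-1.36) and Lgals12 (1.61). Of 7 erythrocyte markers only Bpgm passed (-0.56), and the haemoglobin genes Hba-a2 and Hbb-b2 differed by -0.40 and -0.30 without passing. Of 38 stratified squamous markers 4 were higher in distal and 2 in proximal libraries, with Krt78 (0.67), Sprr1a (-4.56) and Sfn (-1.10) beside Tgm3, and the brightest, Dsp, Perp and Pkp1, differed by 0.20, -0.26 and 0.25 without passing. These lists did not shift (camera adjusted p = 0.0550, 0.417 and 0.290). Among the brightest markers of the other lists, the smooth muscle genes Mylk, Tpm1 and Tpm2 differed by 0.05, 0.08 and 0.11, the plasma cell genes Igha, Jchain and Sdc1 by 0.04, -0.08 and -0.23, and the neuronal genes Stmn3 and Vip by 0.08 and 0.11, all without passing. Snap25 of the neuronal list was higher in distal (1.14) and Fabp2 of the intestinal list in proximal libraries (-1.41), while Mgam (0.16) and Lyz1 (-0.38) did not pass.

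Transcripts of the exocrine pancreas stood high in the libraries labelled proximal 1 and distal 1. The median deviation of 19 acinar cell genes was 3.12 in proximal 1 and 3.11 in distal 1, and -1.68, -1.76, -1.5 and -1.45 in proximal 2, proximal 3, distal 2 and distal 3. The protease gene Prss2 measured 12.19 and 11.68 in that pair and at most 5.14 in the other 4 libraries, and the carboxypeptidase Cpa1 12.42 and 12.43 against at most 6.16. In both libraries 13 of the 19 genes lay at least 2 log2 units above the highest of the other 4. Clps, Pnliprp2, Cela1 and Sycn did not, and were higher in distal 1 and 2 than in proximal 2 and 3 (2.66, 2.51, 1.74 and 1.40). Zg16 lay between 14.50 and 14.60 throughout. Pnliprp2 measured 12.86 in the library labelled distal 3, above 10.77 and 10.33 in distal 1 and 2. Clps measured 12.37 in distal 3, between 13.1 in distal 1 and 11.59 in distal 2. The differences of Clps and Pnliprp2 are therefore not shown to be regional. For Cela1 and Sycn, distal 3 lay near proximal 2 and 3. In the 4 libraries the list shifted towards distal (camera adjusted p = 0.000140, and adjusted p = 0.706 with an estimated correlation), and without distal 1 its adjusted p was 0.618.

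**Figure D3:**
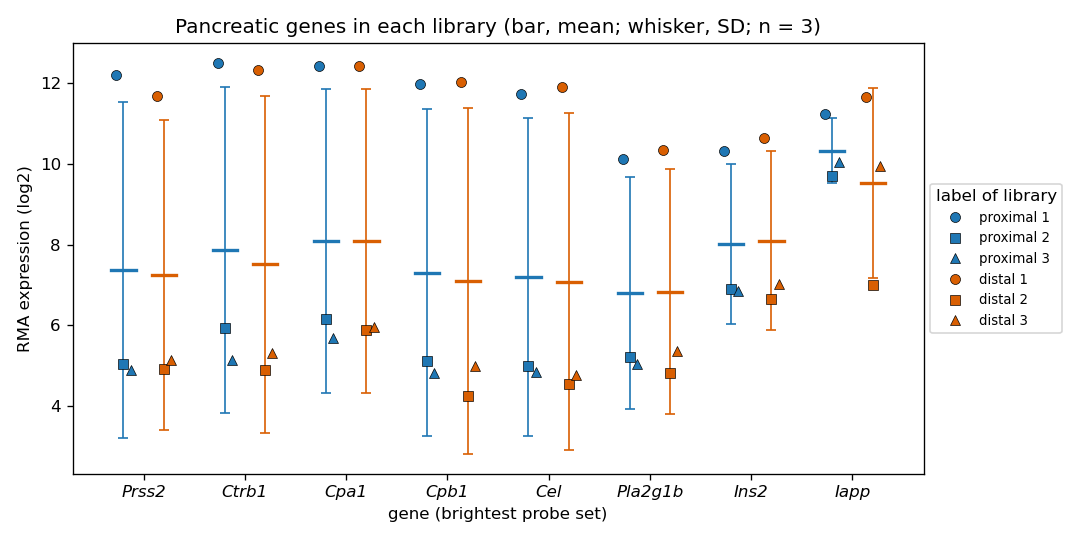
RMA expression (log2, vertical axis) of 8 pancreatic genes in each of the 6 libraries, coloured by label and shaped by replicate number; bars are means and whiskers SDs of 3 libraries. Prss2, Ctrb1, Cpa1, Cpb1, Cel, Pla2g1b and Ins2 are high in proximal 1 and distal 1 and low in the other 4 libraries, with Ins2 at 10.31 and 10.64 against at most 7.02.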

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

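The fit of 4 libraries, leaving out those labelled proximal 1 and distal 3, and its own alternatives were chosen after the result was seen. The count of 0 genes differing between distal and proximal colon was also 0 under the mean of probe sets, quantile normalization, median centring, the trended and robust prior, the dim gene filter, each probe set, the plain test and an adjusted p of 0.01, and was 0 in each of the 6 fits that left out 1 library. Array weights gave 5579 genes, 2227 higher in distal, 3352 higher in proximal and 933 at least 2-fold, and the 4 libraries gave 3494, 1402, 2092 and 1138. Both settings lower or remove the weight of the libraries labelled proximal 1 and distal 3, which by construction changes the spread.

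With the replicate number as a block the count was 0, with 1065 genes at an unadjusted p of 0.05 against 554 without the block and a smallest adjusted p of 0.404, and 11 lists passed. Of 18193 genes, 1065 is only slightly above the share of 0.05 that chance alone gives, and 554 is below it. Deviations from the mean of the label correlated at 0.677, -0.448 and 0.678 between libraries sharing the numbers 1, 2 and 3. Their signs follow the separation on the first principal component, so they cannot tell whether a number names an animal. The main fit had no block because the design text does not say which numbers share an animal. The library labelled distal 3, which stands with proximal 2 and 3 in that separation, correlated best with proximal 2 (0.728).

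The 13 lists called became 5 without dim genes, which tests fewer genes, 0 with the estimated inter-gene correlation and 0 by fry. They ranged from 6 (without distal replicate 2) to 15 (without proximal replicate 1) over the fits that left out 1 library each, with 8 without proximal replicate 3, and were 19 in the 4 libraries. The cause was not tested. Of the 13, the interferon, macrophage, T lymphocyte and smooth muscle lists passed in every fit that left out 1 library. The others each failed in at least 1 such fit, with a highest camera adjusted p from 0.194 (immediate early) to 0.917 (cell division). The absorptive colonocyte list, with a median of -0.07 and an adjusted p of 0.992 as labelled, shifted towards proximal without proximal replicate 1 (adjusted p 0.0327, the lowest over such fits, with 0.907 the highest) and in the 4 libraries (0.00712, median -0.31). So did the anterior Hox list in the 4 libraries (0.0251, median -0.35, against 0.645 and -0.06 as labelled). For these lists the sign of the test changed and that of the median did not. The MHC class II list no longer passed in the 4 libraries (0.737, median -0.03). The pancreatic acinar list shifted towards proximal without distal replicate 1 (0.0442, over such fits 7.1e-05 to 0.95), the library of the distal label with high pancreatic transcripts.

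The Hox order kept its direction, with rho from 0.25 to 0.33 over the fits that left out 1 library each and 0.42 without dim genes, and passed only as Pearson's r of 0.43, where the cause was not tested. No background signal was used here, so levels near the floor have no stated limit.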

Other observations

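All tests below were chosen after the result was seen. The test of a mixture is the 3rd tried: of 2 earlier ones on a position between the proximal pair (0) and the distal pair (1), that on the medians (0.89 in proximal 1 and 0.11 in distal 3) argued against it, and that on the quartiles (0.67 to 1.01 and -0.02 to 0.31) left it open, and the pooled share was chosen after shares per gene had been seen. The tests of carried-over RNA replaced one at 2 log2 units, which left both directions open with 0 and 26 genes. For distal 1 into proximal 1, another test, on the level that the rest of its RNA would need, was dropped because the choice of genes fixed its outcome. The test of a batch no longer includes Hox genes.

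Genes of secreted antibacterial proteins, Retnlb and Ang4, fully followed neither the labels nor the main separation of the libraries. Retnlb, a secreted antibacterial protein, measured 14.32 in the libraries labelled proximal 1 and distal 3, and 12.75, 12.84, 12.15 and 13.64 in proximal 2, proximal 3, distal 1 and distal 2. Ang4, another antibacterial protein, measured 14.98 and 14.89 in that pair, 14.18 and 14.74 in distal 1 and 2, and 12.72 and 11.97 in proximal 2 and 3. It thus followed the main separation except in distal 3. Both genes were chosen after their values were seen. The bacterial poly-A control probe sets, 24 in number, averaged 8.38 and 8.19 in proximal 1 and distal 3, 7.47 and 7.75 in proximal 2 and distal 1, and 7.05 and 7.07 in proximal 3 and distal 2. The 3 probe sets of 18S ribosomal RNA averaged 10.66 and 10.39 in the first of these pairs and 9.42 and 9.21 in the last, with proximal 2 and distal 1 between them. By both levels proximal 1 stands beside distal 3, proximal 2 beside distal 1 and proximal 3 beside distal 2, across the numbers in the titles. Whether such libraries share an animal or a step of processing is not stated, no fit used this order, and an exchange of labels between proximal 1 and distal 3 would leave it as it is.

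The library labelled proximal 1 resembled distal 1 and 2, and the library labelled distal 3 resembled proximal 2 and 3. A batch of amplification or hybridization shared by proximal 1, distal 1 and distal 2 was sought in the controls. Of 42 bacterial and phage control probe sets 0 separated these 3 arrays from the other 3. The 24 poly-A control probe sets followed another order, with distal 2 among the lowest, so they cannot decide on an amplification batch. Of the 18 hybridization control probe sets 0 separated these arrays, which argues against a hybridization batch as far as these probe sets report it. A mixture with at least 0.25 from each region is argued against too: over all called genes higher in the labelled region, the pooled share of that region was 0.132 (bootstrap 95% interval over genes, taken as independent, 0.115 to 0.148) in proximal 1 and 0.111 (0.082 to 0.145) in distal 3, with 0.071 and 0.113 after median centring and, at 2-fold or more, 0.059 and 0.101 as deposited and 0.035 and 0.099 centred, although single genes spread widely (upper quartile 0.433 in proximal 1), and a smaller share stays open. An exchange of the labels of proximal 1 and distal 3 may account for the pattern: both libraries lay nearer the opposite label in 67.6% of the 3494 genes called without them, short of the 80% set for that test, and in 81.0% (922) of the 1138 called at 2-fold or more, with 11 of 11 anterior and 7 of 7 posterior Hox genes, 6 of 6 bile acid, 16 of 16 fatty acid oxidation and 44 of 45 xenobiotic genes, and Hox deviations from the other libraries of the label ran with paralog number at rho = 0.40 in proximal 1 and -0.38 in distal 3, a description across genes that are not independent. These counts and deviations restate the resemblance for which both libraries were left out. They are therefore no separate evidence for an exchange over another cause of that resemblance. Other lists went less with an exchange. Proximal 1 lay nearer the distal pair in 3 of 11 macrophage, 2 of 7 enteric neuron and 2 of 7 immediate early genes. The same held in 2 of 5 cell division and 0 of 2 endothelial genes. Distal 3 lay nearer the proximal pair in 2 of 23 interferon, 4 of 8 smooth muscle and 8 of 14 antimicrobial genes. Calls from 2 libraries per label can reflect single libraries rather than region, so these genes cannot decide against an exchange. An exchange alone does not predict their positions, and whether these come from single libraries was not tested. A true difference in where along the colon the tissue was taken stays open, untested.

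Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. With 0 genes called as labelled, all 10 splits give as many by construction. The highest of the others called 3762, with proximal 1, distal 1 and distal 2 on one side, which points to a structure of the samples that the labels do not describe. It is the grouping already seen in the first principal component of the same arrays, so the count restates it and is no separate evidence.

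Pancreatic transcripts were high in the libraries labelled proximal 1 and distal 1. Pancreatic tissue carried into both may account for this. In both, 13 of 19 acinar genes lay at least 2 log2 units above the highest of the other 4 libraries, which restates the pattern and is no separate evidence. The remaining 6 were either high in other libraries too or, as Prss3, low throughout. Of the islet genes, chosen after their values were seen, Ins2 measured 10.31 and 10.64 against at most 7.02. Iapp measured 11.24 and 11.65, but also 9.7, 10.04 and 9.94 in proximal 2, proximal 3 and distal 3. In distal 2 it measured 7.0, so Iapp sets the pair apart less clearly. RNA of proximal 1 carried over into distal 1 is argued against, as near equal acinar levels would need nearly all RNA of distal 1 to come from proximal 1, and 186 genes lay over 1 log2 unit lower in distal 1, against 6 and 18 between proximal 2 and proximal 3 and 107 and 65 between distal 1 and distal 2. RNA of distal 1 carried over into proximal 1 stays open. The median acinar difference of -0.06 would need a share of 0.959 from distal 1, and 38 genes lay over 1 log2 unit lower in proximal 1. This count is above 18, the larger count of the proximal pair, by less than the 3-fold set for the test. It is below both counts of the distal pair. No biological explanation was tested.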
